A study of Homo sapiens with 6 samples.

How the data were processed

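Gene expression was measured in LNCaP cells, an androgen-sensitive human prostate cancer line derived from a lymph node metastasis, on Illumina BeadChips. Per the labels' protocols, cells growing in RPMI with 10% serum were infected with retrovirus carrying HNF4G or with the empty vector, in triplicate. Infection lasted 3 days and was followed by 2 days of puromycin. Column-purified total RNA (500 ng) was primed with oligo(dT), amplified with T7 polymerase and labelled with biotin. There were 6 samples, 3 per group, and the groups and replicate numbers came from the sample labels. The labels give triplicate infections of 1 cell line, so p-values measure the spread between infected cultures of that line.

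The deposited non-normalized table gives the intensity of each probe in each sample on a linear scale, with a detection p-value that ranks the probe against the negative control beads of its array. Array quantiles differed between samples and the lowest intensity stayed between 67.9 and 72.1, so neither background subtraction nor normalization between arrays was visible in the deposited intensity values. The submitters' processing notes name BeadStudio and Partek, and the steps and their order are not given in the sources used here. A second deposited table holds log2 values that the authors had quantile normalized, as its own values show. Set against the intensities, it was on a log2 scale, with the same sorted values in every column to within 0.0022 and a median of 6.49 in each, and within each array its order followed the intensity. Its direction is therefore that of the intensity, it is not centred per gene, and the target distribution of its normalization stays unknown.

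The non-normalized table held 47323 probes, and 1 line was left out because its intensities were 0 and its detection p-values exceeded 1. A further 1480 lines had no probe identifier. Of the 47322 probes used, 30112 had 1 gene symbol in the platform annotation, 8 had several and 17202 were unnamed in the annotation used. Entrez identifiers matched the RefSeq table of assembly GRCh38.p14 for 30073 probes, and no symbol needed an update. That table served only for names and for the order of neighbouring genes. No coordinates are given.

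Intensities were background-corrected with the normexp model fitted from the detection p-values, given an offset of 16, quantile normalized and log2 transformed (neqc in limma 3.58.1, R 4.3.3). Probes detected at a detection p under 0.05 in at least 3 of the 6 samples were kept, which left 19592 probes, of which 14990 had 1 symbol. The probe with the highest mean over all 6 samples stood for its gene, giving 11267 genes. Among called genes, 88 had more than 1 detected probe and 4 of these had probes of opposite sign. Groups were compared with limma (lmFit and eBayes, two-sided), Benjamini-Hochberg adjustment over all genes tested, and a threshold of 0.05. Differences are HNF4G minus empty vector, on the log2 scale, with their standard error (SE). Other probes of a gene are said to pass or not after adjustment over all 47322 probes in limma, which is stricter. By that measure GNMT, called at adjusted p = 0.013 over genes, had 0.061. Where a gene was detected in no sample of a group, its fold is given as "at least", with the undetected side set, per array, to the higher of its own value and the lowest normalized value of any detected probe. The number of arrays limits the precision, and the median SE of a log2 difference was 0.11.

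There were 25 gene lists, holding 701 genes of which 643 were on the array. They covered gastrointestinal epithelium, gastric and pancreatic secreted proteins, liver secreted proteins, endoderm transcription factors, androgen-induced and androgen-repressed genes, glucocorticoid-responsive genes, androgen metabolism, drug metabolism, lipid transport and oxidation, cholesterol synthesis, fatty acid synthesis, S phase, G2M phase, interferon response, the unfolded protein response, the p53 response, hypoxia and glycolysis, markers of neuroendocrine, basal, luminal, fibroblast or mesenchymal and blood or endothelial cells, ribosomal proteins and oxidative phosphorylation. The 23 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Benjamini-Hochberg adjustment ran over the lists.

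The design, the lists, the first set of alternatives given below and the rule for named genes were fixed before the data were examined. The rule took HNF4G, then the 12 largest rises and the 12 largest falls among called genes with non-overlapping groups that were detected in all 3 samples of at least 1 group, leaving out placeholder symbols. It further took up to 4 measured members of each list with the smallest adjusted p, and a fixed set whatever their values, of which HNF4A, SPINK1, UGT2B15, UGT2B17, KLK3, KLK2, TMPRSS2, FKBP5, FOXA1 and NR3C1 are named in the text and the rest are not reported here. Other genes named in the text were chosen after their values were seen.

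The gene fit and camera were tested on simulated data for this comparison, with 200 of 11267 genes changed for the fit. All of the genes changed by 1 or 2 on the log2 scale were recovered, as were 69.7% of the 66 genes changed by 0.5. Of 185 calls, 5 were false, and 4 of 200 unchanged lists reached an unadjusted p under 0.05 with camera. Simulated genes varied independently, so camera was not tested on correlated genes, such as the interferon list with an estimated correlation of 0.14. Changes were added to normalized values of the genes kept, so background correction, normalization and the detection filter were not tested.

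The first set of alternatives was normexp with an offset of 50, no background correction, median scaling, the authors' normalized values, no filter on dim probes, detection required in all 6 samples, the mean of a gene's detected probes, each probe on its own, a 2-fold minimum, the replicate number as a block, a trended and robust fit, array weights, an estimated correlation and leaving out each sample in turn. Alternatives chosen after seeing the data were leaving out each sample while keeping the genes and probes chosen from all 6 samples, list tests without UGT2B, AKR1C and GSTA genes or without ORM1, and a count of lower genes without the interferon list. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.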

Results

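The series asks how gene expression in LNCaP prostate cancer cells changes when HNF4G, a nuclear receptor normally found in gut, kidney and pancreas, is supplied from a retrovirus. Expression was measured on 6 arrays, 3 from cells given HNF4G and 3 from cells given the empty vector. Between 18855 and 20689 of 47322 probes were detected per sample. Over the 11267 genes tested, samples of 1 group correlated with each other at 0.992 to 0.994 and samples of different groups at 0.983 to 0.986, across genes. The first principal component, which held 54.2% of the variance, separated the groups. HNF4G replicate 3 stood apart on the second (14.5%), at 15.1 against -6.79 and -9.99 for the other HNF4G samples, and had the lowest upper quartile of intensity (122).

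The array held a single named HNF4G probe, ILMN_1743394, and it was detected in none of the 6 samples. Its normalized intensity was 4.22, 4.32 and 4.30 (log2) with the empty vector and 4.28, 4.35 and 4.30 with HNF4G, a difference of 0.03. The position of the probe in the transcript is not known here, and a probe outside the transferred coding sequence would not register it. This probe therefore does not check the labels.

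Cells given HNF4G expressed a set of genes typical of gut and liver that were undetected with the empty vector, and had much lower levels of interferon-stimulated genes. CLRN3, a tetraspan membrane protein, rose from 4.29 ± 0.15 to 9.31 ± 0.01 (log2, SD, n = 3), at least 25.6-fold, and AKR1C3, an enzyme of androgen and prostaglandin metabolism, rose at least 25.2-fold. The steepest fall was in the interferon-stimulated gene IFI27, from 10.02 ± 0.11 to 5.74 ± 0.33, which is 19.4-fold lower with HNF4G. These sizes depend on the background correction, and bounds hold for the one used here. Without it CLRN3 rose by 3.05 in place of 5.02 on the log2 scale and IFI27 changed by -3.14 in place of -4.28, and in the authors' normalized values by 2.92 and -3.02. In total 192 genes were higher and 147 lower (limma, adjusted p under 0.05), of which 67 and 49 changed at least 2-fold. The groups did not overlap in any of these 339 genes, and over all genes tested they did not overlap in 20.03%, against 10% by chance. Among the higher genes, 34 were detected in all 3 HNF4G samples and in no empty vector sample, and among the lower genes 23 showed the opposite. Median scaling in place of quantile normalization gave 265 higher and 113 lower genes, a higher share of 70.1% against 56.6%. Normexp with an offset of 50 gave 251 and 222 (53.1%), and no background correction 241 and 225 (51.7%). Leaving out 1 HNF4G sample left 126, 121 or 118 higher genes, and leaving out 1 empty vector sample left 86, 85 or 78 lower genes.

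**Figure D1:**
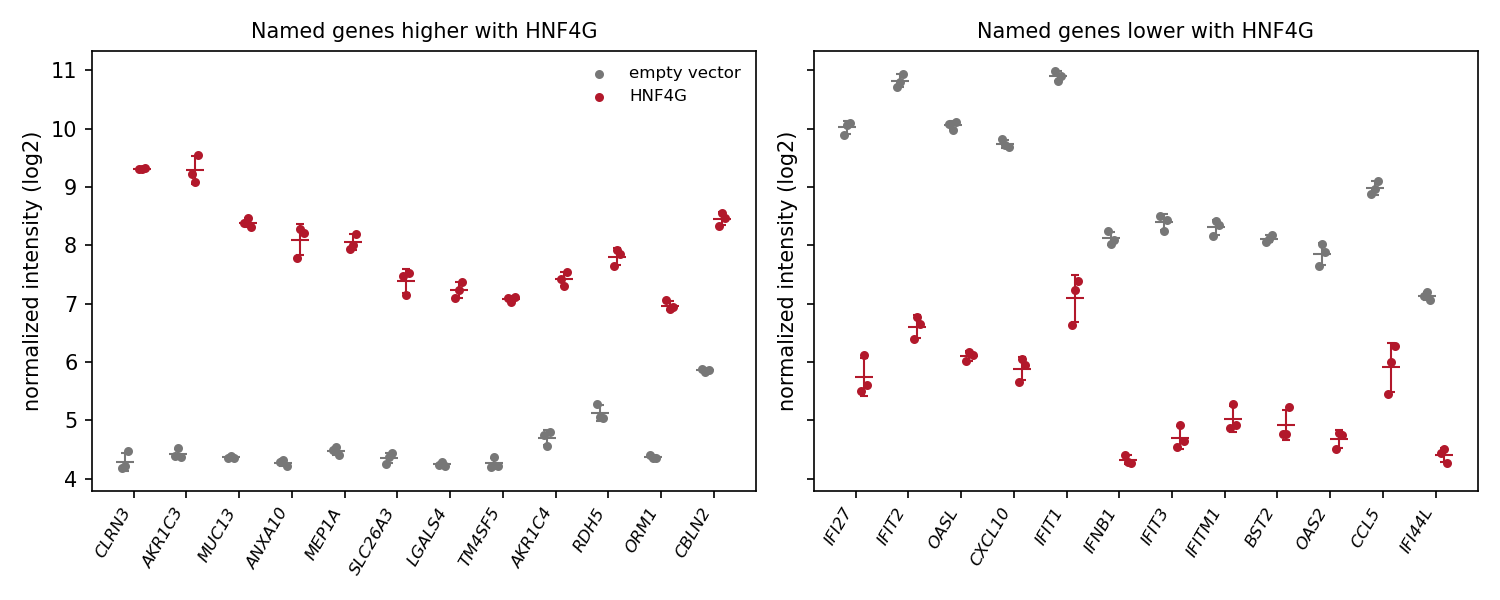
Normalized intensity (log2) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right), with 1 point per sample and bars for the mean and SD of 3 samples per group. CLRN3 lies at 9.31 in the HNF4G samples against 4.29 with the empty vector, and IFI27 at 5.74 against 10.02.

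Genes of the gastrointestinal epithelium rose as a group. Of its 33 genes on the array 21 were detected in too few samples to enter. Of the 12 measured, 8 rose, 1 fell and 3 did not pass, and adjusted over the list alone 10 rose and 1 fell. Of the 8 that rose, 7 were detected in no empty vector sample and entered through their detection with HNF4G, so the filter follows the change and 8 of 12 is not a share of the whole list. The transmembrane mucin MUC13 rose by 4.02 (SE 0.10, adjusted p = 1.1e-09, at least 13.5-fold). The brush-border protease MEP1A rose at least 10.7-fold, the chloride-bicarbonate exchanger SLC26A3 at least 6.74-fold, the galectin LGALS4 at least 6.06-fold and TM4SF5 at least 5.44-fold. CEACAM6, a cell adhesion protein, was at least 1.61-fold lower (adjusted p = 1.3e-03). The mean change of the list was 1.81, or 1.09 with normexp at offset 50, 0.87 without background correction, 0.82 in the authors' normalized values and 0.66 with no filter on dim probes, and the list passed under each. Its median was 2.01, or 1.63 with its 8 genes undetected in a whole group set at their bound. The list shift had an adjusted p of 9.7e-25 in camera and an adjusted p of 0.011 with an estimated correlation. With HNF4G replicate 1, 2 or 3 left out the shift did not pass, at adjusted p = 0.063, 0.072 and 0.064, because a gene seen only with HNF4G then had too few detections to enter. With the genes kept from all 6 samples, a setting chosen after seeing the data, 8 members rose in each of these runs.

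ANXA10, an annexin of gastric epithelium, rose by at least 3.46 on the log2 scale (adjusted p = 1.1e-08), outside that list. Gastric and pancreatic secreted proteins held no rise past the threshold in limma. Of 8 measured, TFF1 was at least 2.49-fold lower, PGC fell by 1.00 on the log2 scale, and 6 did not pass. Adjusted over the list alone, 1 rose and 3 fell, and the list did not pass (adjusted p = 0.071). SPINK1, a trypsin inhibitor, was the 1 that rose adjusted over the list alone, and differed by 0.32 (SE 0.11, adjusted p = 0.18 over all genes in limma). It was dim, at 4.51 with the empty vector and 4.83 with HNF4G, so the size of its difference is uncertain. It was detected in 1 empty vector sample and in all 3 HNF4G samples. Among 6 measured endoderm transcription factors, KLF4 fell by 1.47 on the log2 scale and 5 did not pass, and adjusted over the list alone 1 rose and 1 fell (list adjusted p = 0.41). ONECUT2 was among the 5, and a dimmer ONECUT2 probe rose by 0.82 (adjusted p = 0.039 over all probes). HNF4A was not analysed here.

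Secreted liver proteins were also higher. Of 18 measured members, from 41 on the array, 7 rose, 1 fell and 10 did not pass, and adjusted over the list alone 10 rose and 3 fell. Coagulation factor F5 rose by 2.48 (SE 0.14, adjusted p = 5.8e-07), the ribonuclease ANG by 1.86 (SE 0.11) and the thyroxine carrier TTR by 1.70 (SE 0.13). Complement factor CFB fell by 1.55 on the log2 scale (SE 0.15, adjusted p = 7.3e-05). The list passed with the preset correlation (adjusted p = 1.3e-07) and at adjusted p = 0.025 with an estimated correlation. Its median was 0.44, or 0.27 with 5 genes at their bound. Its mean was 0.49, or 0.27 without background correction, 0.26 in the authors' normalized values and 0.23 with no filter on dim probes. It did not pass when detection was required in all 6 samples (adjusted p = 0.086), which leaves out genes seen in 1 group. ORM1, an acute-phase plasma protein, rose at least 5.05-fold.

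Enzymes that make or inactivate steroids rose, led by near-identical gene families. Of 15 measured androgen metabolism genes, from 26 on the array, 9 rose, 0 fell and 6 did not pass, and the same counts held adjusted over the list alone. At an unadjusted p under 0.05 in limma 9 were higher and 0 lower. The list passed at adjusted p = 2.6e-17, or adjusted p = 0.019 with an estimated correlation. Its median was 0.83, or 0.48 with 3 genes at their bound. UGT2B15 and UGT2B17, which glucuronidate androgens, rose by 2.38 (SE 0.10, adjusted p = 2.7e-08) and 1.48 (SE 0.11, adjusted p = 4.0e-06). UGT2B10 rose by 2.09, UGT2B11 by 1.99 and AKR1C3, also of this list, at least 25.2-fold. AKR1C4, outside the list, rose by 2.72 (SE 0.11). Which UGT2B and AKR1C members changed is uncertain, since probes for such similar transcripts can hybridize to each other's. Without UGT2B, AKR1C and GSTA genes, a setting chosen after seeing the data, 2 of 8 rose, the mean went from 1.19 to 0.29 and the median from 0.83 to 0.13, and the list passed at adjusted p = 0.029 at the preset correlation, the only one tried there.

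In drug metabolism 10 of 27 measured genes, from 57 on the array, rose and 17 did not pass, and adjusted over the list alone 12 rose and 3 fell (list adjusted p = 3.7e-10, or adjusted p = 0.019 with an estimated correlation). The members with the smallest adjusted p were UGT2B15, UGT2B11, UGT2B10 and UGT2B17 again. Without UGT2B, AKR1C and GSTA genes 3 of 18 rose, the mean went from 0.58 to 0.14 and the list did not pass (adjusted p = 0.19). RDH5, a retinol dehydrogenase outside these lists, rose by 2.67 (SE 0.12, adjusted p = 5.0e-08), and CBLN2, a secreted synaptic protein, by 2.59 (SE 0.10).

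Genes that androgen represses rose as a group, while the lower mean of those it induces (-0.14, median -0.26) passed in camera at the preset correlation alone, at adjusted p = 8.5e-04 against 0.26 with an estimated correlation and 0.10 with fry. Of 14 measured repressed genes 6 rose and 8 did not pass, and adjusted over the list alone 6 rose and 1 fell. Besides UGT2B15 and UGT2B17 these included BCHE, which rose by 1.29 (SE 0.10), and DDC, which rose by 0.70 (SE 0.11). The list passed at adjusted p = 3.0e-06 and at adjusted p = 0.043 with an estimated correlation. Without its UGT2B genes the mean went from 0.48 to 0.24 and the median from 0.20 to 0.09, and the list passed at adjusted p = 0.0075 at the preset correlation, the only one tried there. Of 32 measured induced genes, ORM1 rose, 4 fell and 27 did not pass, and adjusted over the list alone 2 rose and 14 fell. ACP3, prostatic acid phosphatase, fell by 0.93 on the log2 scale (SE 0.10, adjusted p = 1.7e-04), GNMT fell by 0.66 and ALDH1A3 fell by 0.60, and a dimmer ALDH1A3 probe differed by -0.36 and did not pass. Without HNF4G replicate 1, 2 or 3, when ORM1 had too few detections to enter, the mean was -0.23, -0.19 and -0.26, and without ORM1 alone, a setting chosen after seeing the data, it was -0.23 (adjusted p = 2.5e-05 at the preset correlation, the only one tried there).

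Several well-known androgen-induced genes did not pass. KLK3, which encodes prostate-specific antigen, differed by -0.09 (SE 0.10, adjusted p = 0.75) and KLK2 by -0.33 (SE 0.10, adjusted p = 0.12). TMPRSS2 differed by -0.09, FKBP5 by -0.12 and the pioneer factor FOXA1 by -0.17. NR3C1, the glucocorticoid receptor, was not detected in enough samples to be tested. Of 13 glucocorticoid-responsive genes, the metallothionein MT2A fell by 0.67 on the log2 scale and 12 did not pass, with 0 rising and 2 falling adjusted over the list alone (list adjusted p = 0.071).

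Interferon-stimulated genes were lower as a group. Of 32 measured members 28 fell, 0 rose and 4 did not pass, and adjusted over the list alone, as at an unadjusted p under 0.05 in limma, 30 fell and 0 rose. OASL fell by 3.95 on the log2 scale (SE 0.10, adjusted p = 1.2e-09), IFIT2 fell by 4.21, IFIT3 fell by 3.70 and the chemokine CXCL10 fell by 3.85. IFIT1, IFITM1, BST2 and OAS2 were 14.0-fold, 9.71-fold, 9.15-fold and 8.98-fold lower. Dimmer probes of IFIT1 and IFIT3 differed by -0.19 and -0.83 and did not pass over all probes. That IFIT1 probe was near background, detected in 2 empty vector samples and 1 HNF4G sample, so it could hardly show a fall. Another dimmer IFIT3 probe changed by -3.24 and passed (adjusted p = 5.1e-06 over all probes). A dimmer OAS2 probe changed by -1.08 and passed (adjusted p = 0.0070 over all probes), while others differed by -0.29 and -0.13 and did not. Of these others, the first was detected in 1 empty vector sample and 0 HNF4G samples. The second was detected in 0 samples of either group, so neither could show a fall. IFI44L was at least 5.77-fold lower by its brightest probe, while its second detected probe differed by -0.06. With empty vector replicate 1, 2 or 3 left out the brightest probe had too few detections to enter and the second stood for the gene, at -0.05, -0.16 and 0.05. With the probes of all 6 samples kept, a setting chosen after seeing the data, IFI44L stayed between -2.78 and -2.64 whichever sample was left out. The mean change of the list was -1.95 (-1.30 in the authors' normalized values) and the median -1.83, with an adjusted p of 7.6e-66 in camera and an adjusted p of 0.011 with an estimated correlation.

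The gene for an interferon itself fell with them. IFNB1 was detected in all 3 empty vector samples at 8.12 ± 0.11 and in no HNF4G sample, which is at least 11.4-fold lower (adjusted p = 1.7e-09). The chemokine CCL5 fell by 3.07 on the log2 scale (SE 0.18, adjusted p = 6.3e-07). No uninfected cells were among the samples, so the level of these genes without a retrovirus is not known here.

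**Figure D2:**
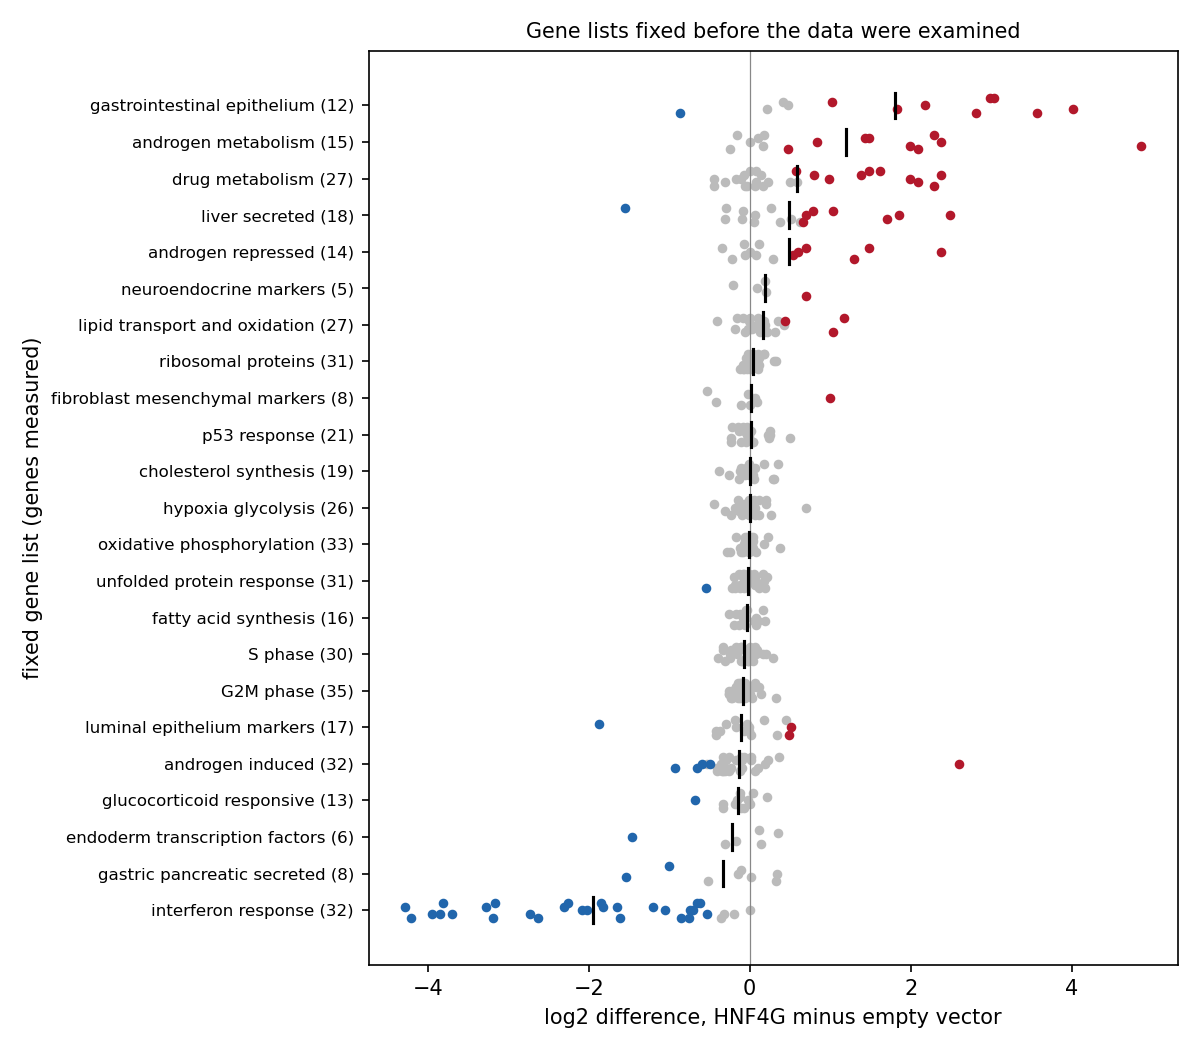
Log2 difference (HNF4G minus empty vector) of each measured gene in the 23 lists with at least 5 measured genes. Points are genes, red or blue where limma called them higher or lower and grey otherwise, and black bars are list means, from -1.95 for interferon response to 1.81 for gastrointestinal epithelium.

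In lipid transport and oxidation 3 of 27 measured genes rose and 24 did not pass, namely the nuclear receptor PPARG by 1.17 (SE 0.11), the peroxisomal oxidase ACOX2 by 1.03 and ACSM3 by 0.44. Adjusted over the list alone 5 rose and 1 fell. This list passed at adjusted p = 0.0013 but had an adjusted p of 0.18 with an estimated correlation. Of 17 luminal markers CD24 rose by 0.49 and KRT8 by 0.51, while MSMB, a prostate secretory protein, fell by 1.87 on the log2 scale, and 14 did not pass (list adjusted p = 0.66). Adjusted over that list alone 4 rose and 5 fell. VIM, an intermediate filament of mesenchymal cells, rose by 0.99 (SE 0.11), the only 1 of 8 fibroblast or mesenchymal markers to pass (list adjusted p = 0.95), with 1 rising and 2 falling adjusted over the list alone. Of 5 neuroendocrine markers DDC alone passed, also adjusted over the list alone (list adjusted p = 0.071). ITGA6, the single basal marker measured, and CD68 and VWF, the 2 blood or endothelial markers measured, did not pass and those lists were not tested. A second CD68 probe, detected in all 6 samples, rose by 0.75 (adjusted p = 0.043 over all probes). Of other probes, 2 for ACSM3 differed by 0.19 and 0.26, 1 for CD24 by -0.04 and 1 for MSMB by -0.44, and none of these passed over all probes. That CD24 probe was near background, detected in 2 samples of each group. That MSMB probe was detected in 3 empty vector samples and 0 HNF4G samples. A further MSMB probe changed by -1.32 and passed (adjusted p = 8.6e-04 over all probes).

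Cell cycle, stress and core metabolic lists held few or no calls in limma. PPP1R15A, a stress-induced phosphatase subunit, fell by 0.54 on the log2 scale, the only 1 of 31 unfolded protein response genes to pass, also adjusted over the list alone (list adjusted p = 0.95). No gene passed among 30 S phase, 35 G2M phase, 21 p53 response, 26 hypoxia and glycolysis, 19 cholesterol synthesis, 16 fatty acid synthesis, 31 ribosomal protein and 33 oxidative phosphorylation genes. The adjusted p of these lists was 0.25, 0.074, 0.82, 0.95, 0.70, 0.88, 0.19 and 0.95 in that order. Adjusted over the list alone 1 hypoxia and glycolysis gene rose and 1 fell, and the other 7 lists held none. A dimmer probe of MSMO1, a cholesterol synthesis gene, rose by 0.44 (adjusted p = 0.026 over all probes). At an unadjusted p under 0.05 in limma 13 of the genes in these lists were higher and 14 lower. The lists differed in balance, with 1 higher and 6 lower in S phase, and 3 higher and 0 lower in the p53 response.

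The fry test asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. It passed 13 of the 23 lists, 7 of the 8 that camera passed at the preset correlation and 6 others. Androgen-induced genes were the exception among the 8. The 6 others were neuroendocrine markers, higher (fry adjusted p = 5.1e-04), and gastric and pancreatic secreted proteins (0.0017), glucocorticoid-responsive genes (0.025), luminal markers (0.025), endoderm transcription factors (0.042) and G2M phase genes (0.042), each lower. In camera, which sets a list against the other genes, these 6 did not pass. Mean, median and camera direction did not share a sign in cholesterol synthesis, the p53 response, hypoxia and glycolysis, oxidative phosphorylation and fibroblast or mesenchymal markers, none of which passed in either test.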

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

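All patterns in this part were chosen after the results were seen, as were the tests of RNA from other cells, of family members, of both RN7SK explanations and of infection. The tests of an outlying array and of background correction or normalization were set before they were run, with the fall of the interferon genes already known.

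Among detected probes with no gene name in the annotation used, 61 were higher and 22 lower with HNF4G, and 7 of the higher probes were detected in all 3 HNF4G samples and in no empty vector sample. These probes lie outside the gene comparisons, and the largest rise among the 7 was 1.26 on the log2 scale.

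Interferon-stimulated genes were lower with HNF4G, 28 of 32 past the threshold. One outlying array is argued against, since the mean change of the list was -1.86 at its weakest with any 1 sample left out. Background correction or normalization is argued against as well, since at least 27 members were called lower under each other correction, scaling or the authors' normalized values. The interferon genes IFNB1, IFNL1 and IFNL2, a count of 3, were detected in all empty vector samples and no HNF4G sample. An interferon response to infection that differed between the cultures for reasons other than HNF4G cannot be told apart from an action of HNF4G. Each vector was carried by its own virus and no uninfected cells were measured. Whether the cells responded through interferon receptors was not tested. The probe for JAK1, a kinase these receptors use, was detected in 0 empty vector samples and 1 HNF4G sample. The receptor genes IFNAR1 and IFNAR2 were detected in all 3 samples of each group.

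Gut and liver genes were higher with HNF4G. RNA from gut or liver cells would bring all their abundant transcripts, yet of 28 such transcripts on the array 4 were called higher (LGALS4, VIL1, APOA1 and TTR), 2 lower and 15 were detected by no probe in any HNF4G sample. ALB, the most abundant liver transcript, differed by -0.30 (adjusted p = 0.23 in limma). Cross-hybridization among members of a gene family stays open, because the annotation gives no probe sequences: 10 of the 15 gut and liver list genes called higher had no called higher gene of the same symbol stem, and 42 of the 67 genes higher by at least 2-fold, the set looked at first. An action of HNF4G stays open and was not tested.

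RN7SK, a small nuclear RNA without a poly(A) tail that was singled out after its values were seen, fell by 2.48 on the log2 scale (SE 0.17, adjusted p = 3.0e-06 in limma). A single faulty probe is argued against, since the second RN7SK probe changed by -3.88 (SE 0.15). For 13 other small non-coding RNAs, detected in all 6 samples and brighter than the median gene, the median change was -0.023 (95% bootstrap interval -0.34 to 0.06). Of these, 0 were called higher and 1 lower, and the lowest change was -0.45. Less carry-over of RNAs without a poly(A) tail is argued against only for RNAs that stayed detected. The detection rule leaves out any that were lost with HNF4G. Over all 129 other small non-coding RNAs tested, the set looked at first, the median was 0.01. That set has no brightness limit, and dim members near background can show little change. No biological explanation was tested.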

How the results depend on the processing

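Alternatives that keep the genes of all 6 samples, drop families or ORM1, or leave out the interferon list were chosen after seeing the data. The 192 higher genes became 118 to 126 with 1 HNF4G sample left out and 131 to 146 with 1 empty vector sample left out, and the 147 lower genes became 78 to 125. With the genes of all 6 samples kept, these ranges were 131 to 157 and 94 to 126. A 2-fold minimum left 67 and 49. Lower genes numbered 222 with normexp at offset 50 and 225 without background correction, of which 124 and 120 were among the 147, and the cause was not tested. Outside the interferon list 119 genes were lower. The undetected HNF4G probe differed by 0.24 under median scaling, which moves all probes of an array by the same amount, undetected ones included. The 95th percentile of intensity was 763 to 902 in HNF4G samples and 926 to 1095 in empty vector samples. The 0.24 is therefore no sign of HNF4G, and how much of it the scaling explains was not tested. Of the 8 lists past the threshold, 6 also passed with an estimated correlation. The mean change of androgen-induced genes (-0.14, adjusted p = 0.26) and of lipid transport and oxidation (0.16, adjusted p = 0.18) did not. Gastrointestinal epithelium had a mean of 0.22 to 0.28 with 1 HNF4G sample left out, against up to 2.08 without an empty vector sample, and liver secreted proteins 0.57 (adjusted p = 0.086) with detection required in all 6 samples, because genes seen in 1 group then drop out. Without background correction the gastrointestinal mean was 0.87 and the liver mean 0.27, and with no filter on dim probes androgen metabolism had a mean of 0.67 and drug metabolism 0.32, all past the threshold. Drug metabolism had a mean of 0.14 without UGT2B, AKR1C and GSTA genes. With 1 sample left out IFI44L ranged from -2.78 to 0.046, the latter (adjusted p = 0.94) without empty vector replicate 3, when its other probe stood for it because the brightest had too few detections. Of 49 named called genes 43 stayed past the threshold in every alternative gene fit that tested them. The 2-fold minimum and each probe on its own are not part of this count. Most were named for large changes or small adjusted p, so the count does not speak for all calls. Only 40 were tested with an HNF4G sample left out, and 33 with detection required in all 6 samples. Of the 192 higher genes, 111 to 118 were called again with an HNF4G sample left out. With the genes of all 6 samples kept, 144 to 148 were. Named called genes such as VIM (0.99) and ACP3 (-0.93) fall short of 2-fold. The replicate block gave 193 higher and 143 lower genes, of which 177 and 135 were among the main calls. The replicate numbers did not pair the samples, since deviations from the group means correlated at -0.01, 0.04 and 0.01, and 1 of 3 HNF4G samples correlated best with its own number. Slide as a block was not run because no slide is named. Signal over background limits the dim genes, of which 34 higher and 23 lower ones have only a bound.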

Other observations

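Apart from BCHE, which the rule for named genes took, the genes in this part were chosen after their values were seen. They are single genes outside the lists, except SI of the gastrointestinal epithelium list and BCHE of the androgen-repressed list. No gene list was tested here. The retinol dehydrogenase RDH16 rose by 0.87 (SE 0.13), the retinal reductase DHRS3 by 1.09 (SE 0.14) and the retinol-binding protein RBP5 by 0.97 (SE 0.11). The alcohol dehydrogenases ADH1A and ADH1C rose by 2.40 (SE 0.12) and 2.41 (SE 0.13), and the signals of these similar genes were not told apart. EGFR, the epidermal growth factor receptor, rose by 0.85 (SE 0.11, adjusted p = 1.1e-03 in limma).

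The chemokine CXCL8 was detected in every empty vector sample and in no HNF4G sample, at least 3.43-fold lower (adjusted p = 1.3e-07 in limma). S100P, a calcium-binding protein, fell by 2.53 on the log2 scale (SE 0.11) and TNFAIP3, an inhibitor of NF-kappaB signalling, fell by 0.51 on the log2 scale (SE 0.12). IFNL1 was at least 5.11-fold lower and IFNL2 at least 1.66-fold lower, 2 similar genes whose probes were not told apart.

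The split of the 6 samples by vector called 339 genes, and the highest of the other splits called 0. Each other split put both vectors in each part. The difference between vectors then counts as spread, so their 0 calls say little. Of the 10 splits only 1 gave as many, and 10 splits are too few for a share under 0.05.

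A hypothesis formed after seeing the called genes was that genes higher with HNF4G lie next to each other among the tested genes in RefSeq order. It was counted on those same genes, so the counts describe what prompted it and are no independent test. The 192 higher genes formed 23 neighbouring pairs, against a mean of 3.25 over 10000 random draws. With 1 gene kept per symbol stem, 159 genes formed 9 pairs against 2.27. Of the 9 pairs 3 came from 1 run of SI, SLITRK3, BCHE and ZBBX, which rose by 1.02, 1.00, 1.29 and 0.56, and another pair was PLAAT3 and ATL3, which rose by 1.32 and 1.29. The 119 lower genes kept by the same rule formed 0 pairs against 1.24, and the difference between the directions was not tested. All 147 lower genes were not counted without that rule, which keeps only 1 of IFIT1, IFIT2 and IFIT3. The 0 pairs therefore do not show that lower genes lack neighbours. Whether neighbouring genes rise together stays open, and related genes with different symbol stems were not removed.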
